A study of Homo sapiens with 17 samples.

How the data were processed

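RNA in 17 human glioma sections was measured with spatial transcriptomics, in which tissue lies on an array of barcoded spots and each spot can hold several cells. Per the labels' protocols, the 11 fresh frozen sections were cut at 10 µm and prepared with the Visium Spatial Gene Expression kit, and the 6 FFPE sections were cut at 5 µm and prepared with the Visium CytAssist kit. The CytAssist kit reads each gene through probes, and the feature files list 18085 genes for FFPE sections and 33538 to 36601 for fresh frozen sections. Sections were grouped by the tumour type in the sample titles and the preparation in the sample descriptions, and the numbers in the titles name replicates.

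The authors deposited UMI counts per gene and spot for spots under tissue, made with Space Ranger and the GRCh38 build per the submitters' processing notes. The notes give Space Ranger 1.1.0 for the 11 fresh frozen sections and no version for the 6 FFPE sections, and they also name Seurat without its role. Per the file headers, Space Ranger 1.0.0 was used for 1 fresh frozen section and 1.1.0 for 10. No other normalization is given in the sources used here, and the values were whole numbers whose totals differed between spots and sections. Each fresh frozen section had its matrix in 2 files with identical entries, of which 1 was used. Sequencing saturation, deposited as a fraction, is the share of reads that repeat a UMI and was 84.1% to 96.0% in fresh frozen and 41.7% to 92.5% in FFPE sections. For the FFPE sections the authors also deposited a score per gene, Moran's I, which measures how alike neighbouring spots are, and for the fresh frozen sections a graph-based cluster of each spot, per the file headers. The capture slide was taken from the letter in the run name in the deposited metrics, which named 3 slides (D, E and G) and none for glioblastoma replicate 1. Slide D held oligodendroglioma replicate 1 and glioblastoma replicates 2 and 3, slide E astrocytoma replicates 1 and 2, the diffuse midline glioma and oligodendroglioma replicate 2, and slide G glioblastoma replicates 4 and 5 and oligodendroglioma replicate 3. A deposited k-means cluster table filed under one section held barcodes of another section and was not used here. Image files were not used here.

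Counts were summed over the spots of each fresh frozen section. Genes were matched by Ensembl identifier over the fresh frozen feature files, which left 32645 shared genes holding 99.3% to 99.95% of UMIs. FFPE sections stayed out of tests between tumour types because probes and direct capture measure genes differently. No pair of sections in a group held counts within sampling noise (chi-square per degree of freedom at least 78.5). Positions and chromosome arms came from a RefSeq gene table of assembly GRCh38.p14 matched by symbol, for 24812 to 25094 genes per fresh frozen section. Arms were divided at approximate textbook centromere positions, so genes close to a centromere may be placed on the wrong arm.

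Tumour types were compared with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation and glmQLFTest), after filterByExpr by group and TMM scaling, in 1 fit of the 11 fresh frozen sections with group as the only factor. The adjusted p threshold was 0.05 with Benjamini-Hochberg adjustment, tests were two-sided, and the standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values (counts scaled to a common library total) used TMM-scaled library sizes in the gene comparisons and plain totals for arm scores, regions and the diffuse midline glioma. The 16 gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01, which compares a list with all other genes. Camera was run again with an estimated correlation, and fry, which tests whether a list's genes move one way, was run as an alternative. The lists were hypoxia, mesenchymal, astrocytic, oligodendrocyte progenitor, neuronal progenitor, proliferation, neuron, myelin, macrophage and microglia, T cell, endothelial, vessel wall and matrix, interferon and MHC class I, red blood cell, immediate early and stress, and HOX genes. Lists, tests, designs, pairs of lists, neighbours of loci and all alternatives except the slide term and leaving out sections from the comparison of EGFR with 7p were chosen before the data were examined. Within-slide values were added after seeing the data, and the slide term gave glioblastoma replicate 1 a level of its own.

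Genes were named by a fixed rule. For each contrast it took the 8 largest log2 fold changes each way among genes past the threshold, with a mean of at least 16 CPM over both groups and groups that did not overlap, up to 3 members with the smallest adjusted p of each list past its test, and 7 locus genes. The rule left out mitochondrial and ribosomal protein genes, immunoglobulin and T cell receptor segments, MHC class II genes, genes with common inherited deletions, sex-linked marker genes and genes without a symbol. A fold against a group with no count in any section was computed against a floor of 3 counts over the group and is a lower bound. With 1 to 3 counts over the group, the ratio to its CPM is given with an exact Poisson interval of that count. HBA1 and HBA2, HSPA1A and HSPA1B, MHC class I genes, CCL3L1, KLRC3 and MTRNR2L12 share sequence with near-identical genes, and their values are uncertain. List members behind a count of 5 or fewer were named after their values were seen, where the rule had not named them. Values of a few genes are not reported here.

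An arm score was the median over arm genes, with at least 10 CPM on average, of log2(CPM + 1) less the gene's mean, after subtracting the section's median over autosomal genes. Arms with at least 30 genes were compared with exact two-sided permutation tests. Within spots, counts were scaled to 10000 per spot and log-transformed, and Pearson correlations were partial on the log of total UMIs. Shares of chromosomes used a pseudocount of 1 and left out list and locus genes. Each locus neighbour was set against 200 random genes drawn from the 400 nearest in mean expression, among genes found in at least 1% of spots, and EGFR also against 20 genes per neighbour on 7p more than 10 Mb away. Moran's I was computed over adjacent spots after thinning each spot to 1000 UMIs, and single genes were ranked among those in at least 10% of spots, with the best 10 named. Regions are the deposited clusters, described by the 3 genes with the largest fold over the rest of the section, with 1 CPM added to both, at 200 CPM or more. For the diffuse midline glioma, genes with at least 50 CPM and 4-fold above or below all other fresh frozen sections were named, with 95% exact Poisson intervals. Within-slide differences of genes and lists are on the log2(CPM + 1) scale. Single-value tests used exact permutation or sign flips over sections.

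Methods were tested on simulated data. For glioblastoma against oligodendroglioma, counts were drawn from the real means and library sizes, and 18406 genes were tested. Of 100 genes changed 2-fold 1% were recovered and of 100 changed 4-fold 39%, with 0 false calls. The real comparison called 5049 genes, and the adjustment is stricter where fewer genes change, so these shares do not describe it. A drop of -0.5 simulated on 1p and 19q was recovered as -0.431 and -0.410 over 10472 genes, where the largest difference of another arm was 0.123. The simulated sections shared 1 mean profile, without differences in cell content or tumour type. The value of 0.123 is therefore no measure of how far arms differ in the real data, where 10p differed by 0.611. Simulated EGFR genes with a shared factor gave a difference of 0.579 and MET genes without one gave 0.00991, and Moran's I was 0.787 for a list raised on one side and -0.0133 for one with no pattern. Alternatives were relative log expression scaling, DESeq2 1.42.0, no filter on low counts, fits of 2 groups, the replicate number as a block, leaving out mitochondrial and ribosomal protein genes, spots with at least 500 UMIs, other arm, correlation and thinning settings, and leaving out each section. Other tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. Intervals cover counting error only.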

Results

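The series holds 17 sections of human glioma profiled with spatial transcriptomics, in which RNA is captured on an array of barcoded spots and counted as unique molecular identifiers (UMIs) per gene and spot. Of these, 11 sections were fresh frozen and 6 were formalin-fixed and paraffin-embedded (FFPE). The fresh frozen sections came from glioblastoma (5 sections), oligodendroglioma (3), astrocytoma (2) and diffuse midline glioma (1), and the FFPE sections were all glioblastoma. A total of 52440 spots lay under tissue, 33573 in the fresh frozen and 18867 in the FFPE sections. Total UMIs per section ranged from 10142519 to 39457080 in fresh frozen glioblastoma, from 10747702 to 13111717 in oligodendroglioma and from 5572453 to 10117287 in astrocytoma. The diffuse midline glioma section held 18353930 UMIs, and the FFPE sections held 7595848 to 95924192. The median UMI count per spot ranged from 1460.5 to 11120 in fresh frozen and from 1173 to 29150 in FFPE sections. Mitochondrial transcripts made up 3.42% to 5.91% of UMIs in fresh frozen glioblastoma, 11.2% to 26.3% in oligodendroglioma and 16.3% to 18.3% in astrocytoma. This share separated glioblastoma from both other groups without overlap. The series concerns loss of chromosome copies and DNA amplified outside the chromosomes, as its title states, and the comparisons follow the tumour types given in the sample titles. The labels do not say whether each tumour came from a different person, so p-values measure the spread between these sections. Tumour types were compared on UMI counts summed per section, and patterns within sections were compared across spots.

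Glioblastoma sections had higher expression of CHI3L1, LTF and LOX than oligodendroglioma sections, and lower expression of the neuronal genes NEFM, PVALB and INA. CHI3L1, a secreted glycoprotein of reactive and mesenchymal glial cells, averaged 4272 ± 3920 CPM (counts scaled to a common library total; SD, n = 5) in glioblastoma and 8.79 ± 3.52 CPM (n = 3) in oligodendroglioma, a log2 fold change of 8.92 ± 1.95 (SE; edgeR adjusted p = 0.0105). LTF, the iron-binding protein lactotransferrin, differed by 9.40 ± 1.57 on the log2 scale (adjusted p = 0.00392), and LOX, which cross-links collagen, by 8.33 ± 1.24 (adjusted p = 0.00265). The acute-phase gene SAA1 and the phospholipase gene PLA2G2A (adjusted p = 0.0273 for each) held 3 and 1 UMIs in all oligodendroglioma sections together, with ratios of CPM of 13324 (95% exact Poisson interval 4559 to 64608) and 39104 (7018 to 1544510). Their fitted log2 fold changes were 13.44 ± 3.77 and 14.78 ± 4.15, and 9.996 and 11.28 without glioblastoma replicate 4, and both lost their call without any one oligodendroglioma section (edgeR adjusted p from 0.0849 to 0.117). The interferon-induced gene GBP5, with 1 UMI in oligodendroglioma, had a ratio of 1112 (199.6 to 43928) and a fitted log2 fold change of 9.64, or 8.55 without glioblastoma replicate 2 and 12.07 and 8.99 without oligodendroglioma replicates 2 and 3, and it lost its call with the capture slide as a further term (edgeR adjusted p = 0.0747). CXCL10 was higher by 8.90 ± 2.14 on the log2 scale and the transcription factor gene DMRTA2 by 8.50 ± 1.34. In the other direction, the neurofilament gene NEFM averaged 2.21 ± 3.31 CPM in glioblastoma and 206 ± 148 CPM in oligodendroglioma (log2 fold change -6.55 ± 1.24, adjusted p = 0.00606). The interneuron calcium-binding protein gene PVALB (-6.44 ± 1.30), the GABA receptor subunit gene GABRG1 (-6.10 ± 1.01) and the neuronal intermediate filament gene INA (-5.71 ± 1.31) were lower as well. So were TESPA1, CRTAC1, VSTM2A and the long non-coding RNA LINC00632, with log2 fold changes from -6.12 to -5.63.

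Among 19092 genes tested with edgeR's quasi-likelihood test (two-sided, Benjamini-Hochberg adjusted), 2510 were higher and 2539 lower in glioblastoma, 5049 in all. Of the 16 gene lists fixed before the data were examined, 9 were higher and 5 lower with limma's camera test at its preset inter-gene correlation, and none passed with an estimated correlation. The proliferation list, genes of DNA replication and mitosis, was higher as a whole (median log2 fold change 4.48, adjusted p = 9.23e-13, and adjusted p = 0.204 with an estimated correlation). All 15 of its genes were higher past the test, also 15 when adjusted over the list alone. Among them, the ribonucleotide reductase subunit gene RRM2 differed by 7.20 ± 0.71, the mitotic regulator gene BIRC5 by 6.88 ± 0.60 and the cyclin-dependent kinase gene CDK1 by 4.81 ± 0.40. The mesenchymal list had a median of 4.14 (adjusted p = 7.06e-09, and adjusted p = 0.377 with an estimated correlation), with 15 of 16 genes higher past the test and 16 adjusted over the list alone. EMP3, a membrane glycoprotein gene, differed by 5.61 ± 0.85 and the annexin gene ANXA2 by 4.53 ± 0.63.

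Vessel wall and matrix genes (median 4.66, adjusted p = 0.000156, and adjusted p = 0.377 with an estimated correlation) were higher for 10 of 14 genes, or 11 adjusted over the list alone. The basement membrane collagen genes COL4A1 and COL4A2 differed by 6.36 ± 1.07 and 5.59 ± 1.01, and the periostin gene POSTN by 8.02 ± 1.41. Hypoxia genes (median 2.03, adjusted p = 0.000286, and adjusted p = 0.404 with an estimated correlation) were higher for 9 of 16, or 11 adjusted over the list alone. The lipid droplet protein gene HILPDA was at 3.89 ± 0.69 and the glycolytic enzyme gene HK2 at 3.78 ± 0.81. Interferon and MHC class I genes (median 2.72, adjusted p = 0.000434, and adjusted p = 0.404 with an estimated correlation) were higher for 10 of 14, or 11 adjusted over the list alone. Among them were ISG15 at 4.09 ± 0.95 and the MHC class I light chain gene B2M at 2.19 ± 0.56. Macrophage and microglia genes (median 2.67, adjusted p = 0.00605, and adjusted p = 0.482 with an estimated correlation) were higher for 7 of 16, or 11 adjusted over the list alone. The lipopolysaccharide co-receptor gene CD14 was at 4.17 ± 1.12. T cell genes (median 2.95, adjusted p = 0.0485, and adjusted p = 0.536 with an estimated correlation) included 2 of 11 higher past the test, CCL5 at 2.95 ± 0.92 and NKG7 at 3.29 ± 1.07. For T cell genes 0 passed adjusted over the list alone, where edgeR gave CCL5 an unadjusted p of 0.00964 and NKG7 one of 0.0119. Immediate early and stress genes (median 1.42, adjusted p = 0.0315, and adjusted p = 0.482 with an estimated correlation) were higher for 5 of 10, or 6 adjusted over the list alone. The transcription factor gene JUN was at 1.90 ± 0.36, and the others past the test were EGR1, FOS, ATF3 and IER2.

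HOX genes, transcription factors of body axis patterning, were higher for 14 of 24 genes tested, or 18 adjusted over the list alone (adjusted p = 2.17e-08 for the list, and adjusted p = 0.0901 with an estimated correlation). In oligodendroglioma 14 of these 24 genes had a count of 0 in every section, so their folds are lower bounds against a floor of 3 counts over the group. With those genes at their bound, the list's median log2 difference was 4.51, against 7.30 as fitted. HOXD9 was at least 166-fold higher in glioblastoma, HOXD10 at least 113-fold and HOXD8 at least 22.5-fold.

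Neuron genes were lower as a list (median -4.85, adjusted p = 7.06e-09, and adjusted p = 0.377 with an estimated correlation), and all 14 were lower past the test, also 14 adjusted over the list alone. Neuronal progenitor genes (median -1.75, adjusted p = 0.00459, and adjusted p = 0.377 with an estimated correlation) were lower for 5 of 13, also 5 adjusted over the list alone. The microtubule regulator gene STMN2 was at -4.79 ± 0.96, and ELAVL4, STMN4, NNAT and HES6 were the others. Oligodendrocyte progenitor genes (median -1.96, adjusted p = 0.00637, and adjusted p = 0.377 with an estimated correlation) were lower for 4 of 13, also 4 adjusted over the list alone. OMG, the oligodendrocyte myelin glycoprotein gene, was at -3.50 ± 0.47 and TNR, a perineuronal matrix gene, at -4.21 ± 1.098. APOD and OLIG1 were the others. The myelin list was lower (median -2.08, adjusted p = 0.000471, and adjusted p = 0.404 with an estimated correlation). Of its genes 2 of 14 passed the test over all genes, among them CNP at -1.28 ± 0.37, and 0 passed adjusted over the list alone. The red blood cell list was lower (median -4.40, adjusted p = 0.0179, and adjusted p = 0.377 with an estimated correlation) in all 3 of its haemoglobin genes, also 3 adjusted over the list alone. HBA1 and HBA2 have nearly identical transcripts, so their separate values are uncertain. The astrocytic list (median -0.13, adjusted p = 0.602) did not pass, with 1 gene lower past the test, also 1 adjusted over the list alone, the glycolytic enzyme gene ALDOC at -3.17 ± 0.67. The endothelial list (median 1.60, adjusted p = 0.0741) did not pass either, with 4 genes higher, PLVAP, ESM1, ENG and PECAM1, or 5 adjusted over the list alone, which adds CDH5 at 1.72 ± 0.61. The neuron, myelin and red blood cell lists mark other cells that a section can hold, and the mitochondrial share moved with them, at 3.42% to 5.91% of UMIs in glioblastoma against 11.2% to 26.3% in oligodendroglioma. None of the 7 genes of frequently amplified loci passed, with EGFR, a growth factor receptor gene, at 1.49 ± 0.81 (adjusted p = 0.195).

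**Figure D1:**
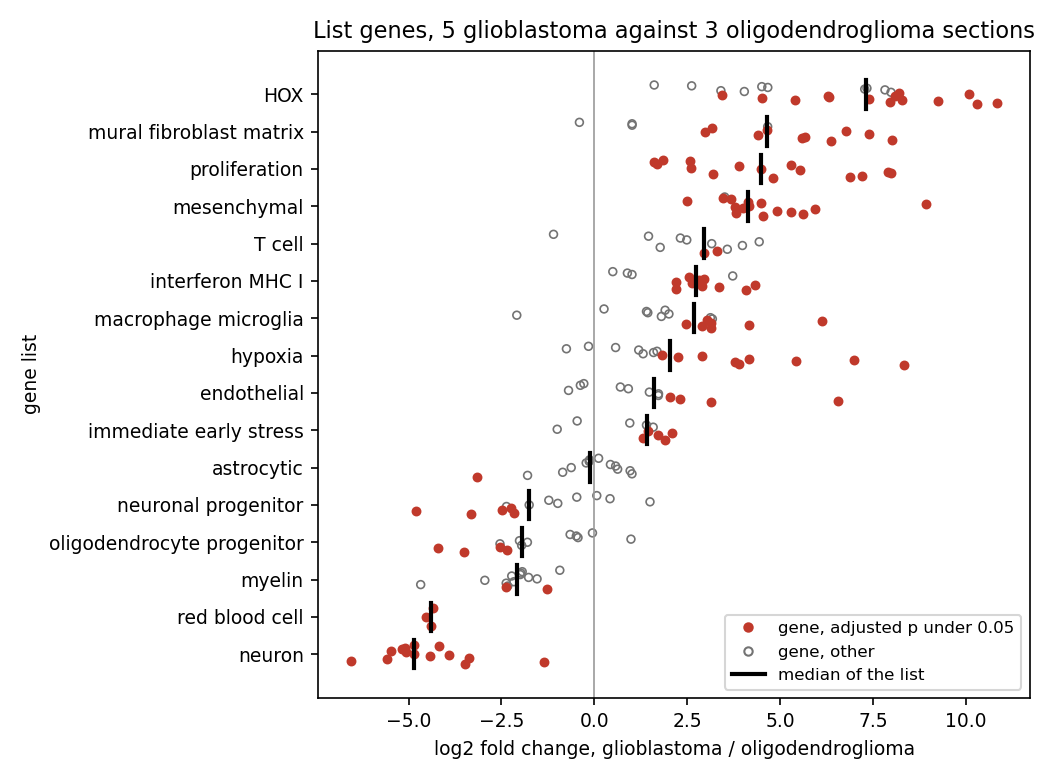
Log2 fold change of each list gene between 5 glioblastoma and 3 oligodendroglioma fresh frozen sections, by gene list, with red points for genes past the edgeR test, open points for the others and a black bar at the list's median. The medians run from -4.85 for neuron genes to 7.30 for HOX genes as fitted, of which 14 have a count of 0 in oligodendroglioma and a lower bound in place of a fold.

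With the capture slide as a further term, chosen after seeing the data, 634 genes passed, and of 54 genes past the test that the fixed rule named, 8 kept their call (34 without oligodendroglioma replicate 1). Slides D and G each held 2 glioblastoma sections and 1 oligodendroglioma section. Within them the list medians on the log2(CPM + 1) scale were 3.73 and 2.83 for proliferation, 4.36 and 3.95 for mesenchymal and -4.61 and -4.96 for neuron genes. They were -2.93 and -1.90 for myelin, -7.33 and -1.86 for red blood cell, 0.324 and 1.47 for T cell and 1.35 and 1.49 for HOX genes. This scale shrinks differences of genes at low counts, such as T cell and HOX genes, so these values cannot be set against fitted folds. Leaving out 1 section moved the fitted fold of 26 of the 54 genes by over 1.5 times. Without glioblastoma replicate 3 the log2 fold changes were -8.38 for CRTAC1, -8.21 for NEFM, -8.01 for PVALB, -7.47 for INA, -7.22 for GABRG1, -6.66 for LINC00632, -6.55 for VSTM2A and -6.06 for STMN2. Without oligodendroglioma replicate 3 they were 9.18 for RRM2, 7.86 for BIRC5, 9.96 for CXCL10, 9.22 for DMRTA2, 8.77 for LTF, 4.93 for CD14, 4.40 for HK2 and 3.89 for NKG7. Without oligodendroglioma replicate 2 they were -5.80 for NEFM, -5.60 for PVALB, -5.10 for TESPA1 and -5.01 for VSTM2A, and without replicate 1 they were 11.36 for LTF, -5.36 for CRTAC1 and -5.09 for LINC00632. CHI3L1 was at 8.19 without glioblastoma replicate 5 and CXCL10 at 8.19 without replicate 2, and the 3 haemoglobin genes lost their call without oligodendroglioma replicate 1 (edgeR adjusted p from 0.0722 to 0.110). Without oligodendroglioma replicate 2 the count was 2300 and without replicate 1 it was 2715. The T cell list no longer passed without any one oligodendroglioma section (adjusted p from 0.0526 to 0.0937) or glioblastoma replicate 4 or 5 (0.125 and 0.109), nor the stress list without glioblastoma replicate 4 (0.0863) or oligodendroglioma replicate 3 (0.0627). The median log2 fold change of all genes was 0.117, or 0.0674 with relative log expression scaling, and the folds above include this shift.

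Glioblastoma sections had higher expression of the cell division genes TPX2, PTTG1 and BIRC5 than astrocytoma sections, and lower expression of CDKN2A. TPX2, a spindle assembly factor gene, averaged 42.1 ± 22.3 CPM (SD, n = 5) in glioblastoma and 3.74 ± 0.543 CPM (n = 2) in astrocytoma, a log2 fold change of 3.48 ± 0.60 (edgeR adjusted p = 0.0418). PTTG1, the securin gene of chromosome separation, was higher by 3.56 ± 0.63 and BIRC5 by 3.09 ± 0.56. Carbonic anhydrase gene CA3 (6.001 ± 1.08), MOXD1 (4.94 ± 0.76), the metalloproteinase gene ADAM33 (4.73 ± 0.62) and the long non-coding RNAs CYTOR (3.95 ± 0.64) and SNHG18 (3.73 ± 0.65) were also higher. CDKN2A, which encodes cell cycle inhibitors, averaged 2.47 ± 1.98 CPM in glioblastoma and 81.4 ± 7.38 CPM in astrocytoma (log2 fold change -5.06 ± 0.68, adjusted p = 0.0330). The fatty acid desaturase gene SCD (-2.52 ± 0.44), OMG (-2.77 ± 0.49), NDN (-3.47 ± 0.61), PHYHIPL (-2.86 ± 0.54) and MYORG (-2.92 ± 0.57) were lower as well. KLRC3 (-5.63 ± 0.93) and the chemokine gene CCL3L1 (-3.63 ± 0.60) were lower too, but each has a near-identical paralog with which reads can be shared.

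In all, 55 genes were higher and 132 lower in glioblastoma than in astrocytoma, 187 of the 19092 tested. The proliferation list was higher (median 2.69, adjusted p = 1.59e-13, and adjusted p = 0.191 with an estimated correlation), with 5 of 15 genes past the test over all genes and 15 adjusted over the list alone. The cyclin gene CCNB1 was at 2.69 ± 0.46 and the thymidylate synthase gene TYMS at 2.15 ± 0.37, and TPX2, BIRC5 and CDK1 were the others past the test. HOX genes were higher as a list (median 2.54, fitted and with genes at their bound, adjusted p = 8.11e-05, and adjusted p = 0.191 with an estimated correlation), with 1 of 24 past the test and 1 adjusted over the list alone. This was HOXD10, which was at least 49.7-fold higher. The mesenchymal (median 0.98, adjusted p = 4.29e-05), vessel wall and matrix (1.71, adjusted p = 0.0109), hypoxia (0.62, adjusted p = 0.0295) and interferon and MHC class I lists (1.42, adjusted p = 0.0484) were higher by the list test, each with adjusted p = 0.660 with an estimated correlation. None of the genes of these lists passed over all genes, and adjusted over the list alone 1 vessel wall and matrix gene passed, POSTN. EMP3 of the mesenchymal list had a log2 fold change of 2.22 ± 0.84 (edgeR adjusted p = 0.203, unadjusted p = 0.0244) and POSTN 7.30 ± 1.66 (adjusted p = 0.0712). The myelin list was lower (median -3.31, adjusted p = 4.29e-05) and so was the neuron list (median -1.40, adjusted p = 0.000814), each with adjusted p = 0.660 with an estimated correlation. For myelin, 0 genes passed over all genes and 10 adjusted over the list alone, and CNP had a value of -1.49 ± 0.41 with an unadjusted edgeR p of 0.00437. For neuron genes 0 passed in either adjustment, and GAD1, a GABA synthesis gene, was at -1.90 ± 0.72 with an unadjusted edgeR p of 0.0243. The mitochondrial share moved with these lists, at 3.42% to 5.91% in glioblastoma against 16.3% to 18.3% in astrocytoma. None of the 7 locus genes passed, with EGFR at 1.78 ± 0.97 (adjusted p = 0.357).

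The number of genes was 3 without glioblastoma replicate 1 or replicate 2, 5 without replicate 5, 49 without replicate 4, 284 without replicate 3, 7 without astrocytoma replicate 1 and 507 without astrocytoma replicate 2. DESeq2 called 1755, of which 44.7% were higher against 29.4% with edgeR. No slide held both groups, with the slide as a term 0 genes passed in edgeR (692 at an unadjusted p under 0.05), and a fit of the 2 groups alone gave 2 genes. Of the 19 genes past the test that the fixed rule named, TPX2 and CDKN2A among them, 0 kept their call in edgeR with the slide term, in the fit of the 2 groups alone, or without glioblastoma replicate 2 or astrocytoma replicate 1 (16, 19, 19 and 17 at an unadjusted p under 0.05). The number that kept it was 1 without glioblastoma replicate 1 or replicate 5 and 7 without replicate 4, against 19 in DESeq2 on all sections. Leaving out 1 section moved the fold of 13 of the 19 by over 1.5 times, mostly an astrocytoma section. Without astrocytoma replicate 1 the log2 fold changes were -0.62 for MYORG, -0.72 for PHYHIPL, -1.42 for OMG, -1.76 for SCD, -2.47 for NDN and -4.13 for KLRC3, and 6.17 for ADAM33, 5.30 for CA3, 4.34 for MOXD1, 3.35 for CYTOR and 3.01 for SNHG18. Without astrocytoma replicate 2 they were -3.76 for MYORG, -3.69 for PHYHIPL, -3.45 for OMG and -6.34 for KLRC3, and 7.07 for CA3, 5.77 for MOXD1, 4.94 for SNHG18, 4.86 for CYTOR and 4.14 for ADAM33. CDKN2A was at -5.68 without glioblastoma replicate 5, and CCL3L1 at -4.26 and CA3 at 5.41 without replicate 4. Among the lists, the mesenchymal (adjusted p = 0.730), vessel wall and matrix (0.432), interferon and MHC class I (0.462), neuron (0.115) and HOX lists (0.0676) no longer passed without astrocytoma replicate 1, where the hypoxia test pointed the other way (0.208). The myelin list no longer passed without astrocytoma replicate 2 (0.421). Leaving out a glioblastoma section ended the hypoxia call (replicates 2 and 3, 0.101 and 0.0920), the vessel wall and matrix call (replicate 5, 0.0688) and the interferon call (replicates 1 and 2, 0.140 and 0.220), which also ended with no filter on low counts (0.0564). The slide term ended the neuron (0.268) and interferon calls (0.373).

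Between astrocytoma and oligodendroglioma a single gene passed, GNG12, which encodes a G protein gamma subunit. It averaged 47.0 ± 7.12 CPM (SD, n = 2) in astrocytoma and 9.05 ± 2.22 CPM (n = 3) in oligodendroglioma, a log2 fold change of 2.38 ± 0.25 (edgeR adjusted p = 0.0447). By the list test, 9 lists were higher and 3 lower in astrocytoma, with no list passing with an estimated correlation. The mesenchymal list (median 3.25, adjusted p = 8.62e-07) and macrophage and microglia list (3.13, adjusted p = 3.66e-05) were higher, each with adjusted p = 0.415 with an estimated correlation. Adjusted over the list alone, 13 of 16 mesenchymal and 11 of 16 macrophage and microglia genes passed, and over all genes 0 did. On slide E, with 2 astrocytoma sections and 1 oligodendroglioma section, GNG12 differed by 1.96 on the log2(CPM + 1) scale. The list medians there were 2.81 for mesenchymal, 2.59 for macrophage and microglia, -3.92 for neuron and 0.342 for HOX genes (all 24). This scale shrinks differences of genes at low counts, so the HOX value cannot be set against fitted folds. The values of TIMP1, a metalloproteinase inhibitor gene, and of CD14 were 5.33 ± 1.13 (edgeR adjusted p = 0.112, unadjusted p = 0.000865) and 4.49 ± 1.22 (adjusted p = 0.139).

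The proliferation (median 1.04, adjusted p = 3.65e-07), vessel wall and matrix (2.95, adjusted p = 0.00165), T cell (3.40, adjusted p = 0.000795), immediate early and stress (2.24, adjusted p = 0.000458) and HOX lists (adjusted p = 0.000155) were higher in astrocytoma, each with adjusted p = 0.415 with an estimated correlation. Their genes past the test adjusted over the list alone numbered 8, 6, 2, 6 and 3, and over all genes 0 did. The T cell genes were CCL5 at 4.45 ± 1.06 and NKG7 at 4.97 ± 1.22, and the HOX genes were HOXD8, HOXD9 and HOXB7. Of the 24 HOX genes 11 had at most 3 counts in each group and are given no fold, and over the other 13 the median was 3.08 with genes at 0 in oligodendroglioma at their bound, against 5.11 as fitted. The hypoxia list (1.98, adjusted p = 0.00263, and adjusted p = 0.481 with an estimated correlation) and the interferon and MHC class I list (1.01, adjusted p = 0.00710, and adjusted p = 0.485 with an estimated correlation) were higher, with 7 and 0 genes past the test adjusted over the list alone. The neuron list (median -3.20, adjusted p = 6.81e-07), oligodendrocyte progenitor list (-0.38, adjusted p = 0.00826) and neuronal progenitor list (-0.44, adjusted p = 0.0244) were lower, each with adjusted p = 0.415 with an estimated correlation, and 2, 0 and 0 of their genes passed adjusted over the list alone. These were THY1, a neuronal surface glycoprotein gene, at -2.07 ± 0.34 (edgeR adjusted p = 0.0828, unadjusted p = 0.000114) and CHN1 at -3.30 ± 0.68. The myelin list did not pass (adjusted p = 0.810), and its test pointed down while its median (1.12) and mean (1.002) lay above 0, and without astrocytoma replicate 1 it passed pointing up (adjusted p = 0.0112). The endothelial list had an adjusted p of 0.546, with a median of -0.03, a mean of 0.60 and a test pointing up.

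Without astrocytoma replicate 2 or any one of the oligodendroglioma replicates 0 genes passed in edgeR between astrocytoma and oligodendroglioma (1565 to 3433 at an unadjusted p under 0.05), as with the slide term (2017 unadjusted), relative log expression scaling (3382) and a fit of the 2 groups alone (2847). Without astrocytoma replicate 1 971 genes passed, against 1623 in DESeq2 on all sections. Without astrocytoma replicate 2 the mesenchymal, vessel wall and matrix, and interferon and MHC class I lists (adjusted p = 0.120 each), the macrophage and microglia (0.0667), T cell (0.248) and oligodendrocyte progenitor lists (0.784) no longer passed. There the hypoxia (0.519) and neuronal progenitor tests (0.934) pointed the other way. The neuronal progenitor call also ended without oligodendroglioma replicate 3 (0.0579), and the slide term ended the hypoxia and neuronal progenitor calls (0.0789 each) and the oligodendrocyte progenitor call (0.120).

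Expression along whole chromosome arms was compared because joint loss of 1p and 19q defines oligodendroglioma, and gain of chromosome 7 with loss of chromosome 10 is common in glioblastoma. In glioblastoma sections, genes of chromosome 10 were expressed at lower levels than in the 6 other fresh frozen sections, by -0.767 on the log2 scale for 10p (mean score -0.437 ± 0.140 against 0.330 ± 0.249; SD, n = 5 and 6) and by -0.736 for 10q. Genes of chromosome 7 were higher, by 0.404 for 7p and 0.351 for 7q. Within slides D and G, each with 2 glioblastoma sections and 1 oligodendroglioma section, the differences were -0.887 and -0.692 for 10q and 0.385 and 0.340 for 7p. All 5 glioblastoma sections lay below all others for 10p and 10q and above all others for 7p and 7q. The exact two-sided permutation test gave p = 0.00216 for 7p, the smallest it can give, and p = 0.00433 for 7q, 10p and 10q, with adjusted p = 0.0211 for all 4 over 39 arms. In total 13 arms passed, and the number was 8 without glioblastoma replicate 1, oligodendroglioma replicate 1 or oligodendroglioma replicate 2. Higher arms also included 19q (0.618), 19p (0.360) and 21q (0.221), and lower arms 9p (-0.401), 18q (-0.185), 8p (-0.141), 15q (-0.138), 2p (-0.103) and 2q (-0.0945). Neuron and myelin lists and the mitochondrial share also differed between glioblastoma and the oligodendroglioma and astrocytoma sections. How far cell content or RNA quality shifts the scores of these arms was not tested.

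In oligodendroglioma the 594 genes measured on 1p were lower by -0.446 (mean score -0.328 ± 0.128 against 0.118 ± 0.0261; SD, n = 3 and 8), and all 3 sections lay below all 8 others. The 365 genes of 19q were lower by -0.490 (-0.355 ± 0.111 against 0.135 ± 0.334). The exact two-sided permutation test gave p = 0.00606 for 1p, the smallest it can give, and p = 0.0424 for 19q. Neither passed adjustment over 39 arms (adjusted p = 0.236 for both), and 0 arms passed, where the smallest p the design allows is 0.00606. Chromosome 10 differed by more, upward, at 0.611 for 10p and 0.588 for 10q (exact permutation p = 0.0545 and 0.0727). Both arms were low in the 5 glioblastoma sections among the 8 others. All 3 oligodendroglioma sections lay above all 8 others for 6q and 12q, by 0.151 and 0.120 (exact permutation p = 0.0182 and 0.0364). With genes of at least 50 CPM the 19q difference was -0.311 (exact permutation p = 0.133). Leaving out 1 section at a time gave 19q an exact permutation p from 0.00833 without the diffuse midline glioma to 0.156 without oligodendroglioma replicate 3, under 0.05 in 1 of 11 cases, and 1p one from 0.00833 to 0.0222. Within slides D, E and G, each with 1 oligodendroglioma section, 1p differed from the other sections by -0.489, -0.307 and -0.534, and 19q by -0.638, -0.0680 and -0.734. Slide E was the one without glioblastoma, in which 19q was high (mean score 0.338 ± 0.164, SD, n = 5), and its other sections had a mean 19q score of -0.204.

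**Figure D2:**
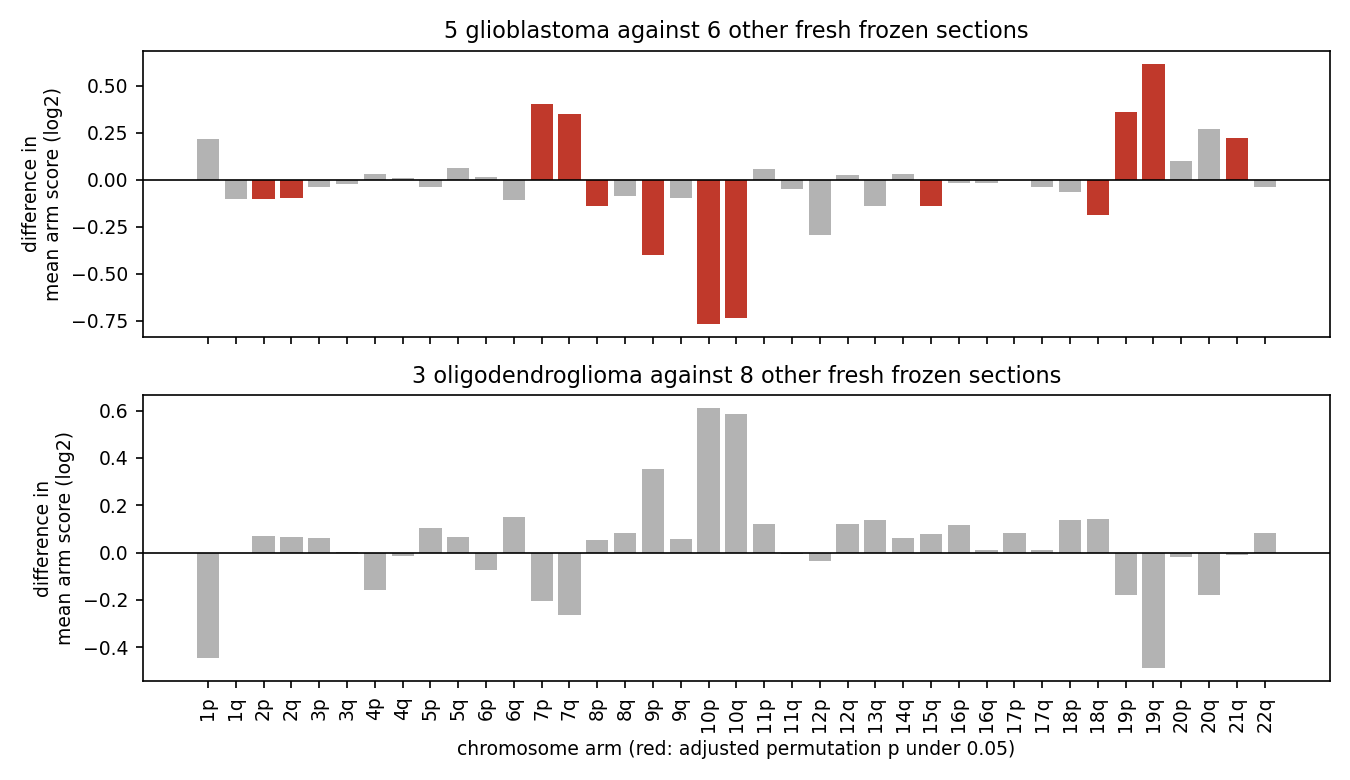
Difference in mean arm score on the log2 scale for each of 39 chromosome arms, for 5 glioblastoma sections against 6 other fresh frozen sections (top) and 3 oligodendroglioma sections against 8 others (bottom), with red bars for arms past the adjusted exact permutation test. Chromosome 10 lies lowest for glioblastoma at -0.767 and -0.736, and no arm passes for oligodendroglioma. There 1p and 19q lie at -0.446 and -0.490, and 10p and 10q differ by more, at 0.611 and 0.588.

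Within glioblastoma sections, the correlation across spots between the shares of UMIs from chromosomes 7 and 10 lay below the median over all pairs of autosomes in each section, at a mean percentile of 9.05 (0.866 to 34.2). The partial correlation itself averaged -0.0872 ± 0.161 (SD, n = 11 sections) and lay above 0 in 4 of 11, against a mean of 0.117 for that median. It averaged -0.166 in fresh frozen sections, with 0 of 5 above 0, and -0.0215 in FFPE sections, with 4 of 6 above 0, where the medians over pairs averaged 0.0212 and 0.196. The correlation less that median averaged -0.204 ± 0.127 (SD, n = 11 sections), and it lay below 0 in 11 of 11. The exact two-sided sign-flip permutation test gave p = 0.000977, the smallest that 11 sections allow. The mean was -0.187 in the 5 fresh frozen and -0.218 in the 6 FFPE sections, and the difference between the preparations did not pass (exact permutation p = 0.710). With each share taken as a mean over genes the mean was -0.334. In the other fresh frozen sections the correlation of chromosomes 7 and 10 less the median lay above 0, which was not tested. It averaged 0.0578 in oligodendroglioma (3 of 3) and 0.0390 in astrocytoma (2 of 2), and was 0.0423 in the diffuse midline glioma. The pair of arms 1p and 19q lay below the median over pairs of arms in the same glioblastoma sections too, by -0.181 ± 0.209 (above 0 in 1 of 11, not tested), and by -0.245 in the fresh frozen ones (0 of 5). This measure of 1p and 19q in oligodendroglioma differed from that in the other fresh frozen sections by -0.0734 (exact permutation p = 0.661, n = 3 and 8). It was 0.266 with shares as means over genes (exact permutation p = 0.00606), so the direction depended on how the share was computed. It was 0.126 without oligodendroglioma replicate 2 (exact permutation p = 0.444) and -0.308 without replicate 3 (exact permutation p = 0.0444). Within slides the difference was -0.0554 on D, -0.464 on E and 0.356 on G, each with 1 oligodendroglioma section.

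EGFR (ENSG00000146648; GRCh38 chromosome 7, 55019017 to 55211628), a receptor gene often amplified in glioblastoma, tended to be expressed in the same spots as its chromosomal neighbours, to a degree that differed between sections. Its mean correlation across spots with 5 neighbouring genes, among them LANCL2 and SEC61G, was 0.135 ± 0.125 (SD, n = 11 glioblastoma sections), against 0.0261 ± 0.0280 with random genes of similar expression. The difference was 0.109 ± 0.124 and lay above 0 in 11 of 11 sections (exact sign-flip permutation p = 0.000977, the smallest possible; adjusted p = 0.00684 over 7 loci). It ranged from 0.00701 to 0.390 between sections, and it averaged 0.111 in fresh frozen sections, or 0.0409 without replicate 1, and 0.107 in FFPE sections. In 3 oligodendroglioma sections the difference averaged 0.00498 ± 0.00753, with a highest value of 0.0133, and in 2 astrocytoma sections -0.00433 ± 0.00797, neither of which was tested. Fresh frozen glioblastoma replicates 3 and 4, at 0.00809 and 0.00701, lay below that highest oligodendroglioma section. The receptor genes MET (chromosome 7, 116672196 to 116798377; 0.0296 ± 0.0548, above 0 in 9 of 11 sections, adjusted p = 0.205) and PDGFRA (chromosome 4, 54229293 to 54298245; 0.00939 ± 0.0180, 8 of 11, adjusted p = 0.289) did not pass the exact sign-flip permutation test. Neither did the p53 regulator gene MDM2 (chromosome 12, 68808172 to 68850686; 0.0223 ± 0.0716, 6 of 11, adjusted p = 0.677) or the cell cycle kinase gene CDK4 (chromosome 12, 57747727 to 57752310; 0.00121 ± 0.00656, 6 of 11, adjusted p = 0.816). The transcription factor genes MYC (chromosome 8, 127735434 to 127742951; 0.000810 ± 0.0224, 5 of 11, adjusted p = 0.902) and MYCN (chromosome 2, 15940550 to 15947004; -0.00157 ± 0.0108, 5 of 11, adjusted p = 0.816) did not pass either. Leaving out 1 section moved the mean of each of these 6 loci by over 1.5 times, with MDM2 at 0.000799 without glioblastoma replicate 11 and MET at 0.0181 without replicate 9. Without glioblastoma replicate 8 MET passed as well, at 0.0347 (exact permutation, adjusted p = 0.0342). The highest single section, an FFPE one, reached 0.237 for MDM2 and 0.145 for MET. A test of the mean over sections cannot exclude shared spots confined to 1 section. For PDGFRA the diffuse midline glioma section had a difference of 0.0791, against at most 0.0415 in glioblastoma (not tested). With 5 fresh frozen or 6 FFPE sections alone the adjusted p of EGFR was 0.438 and 0.109.

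**Figure D3:**
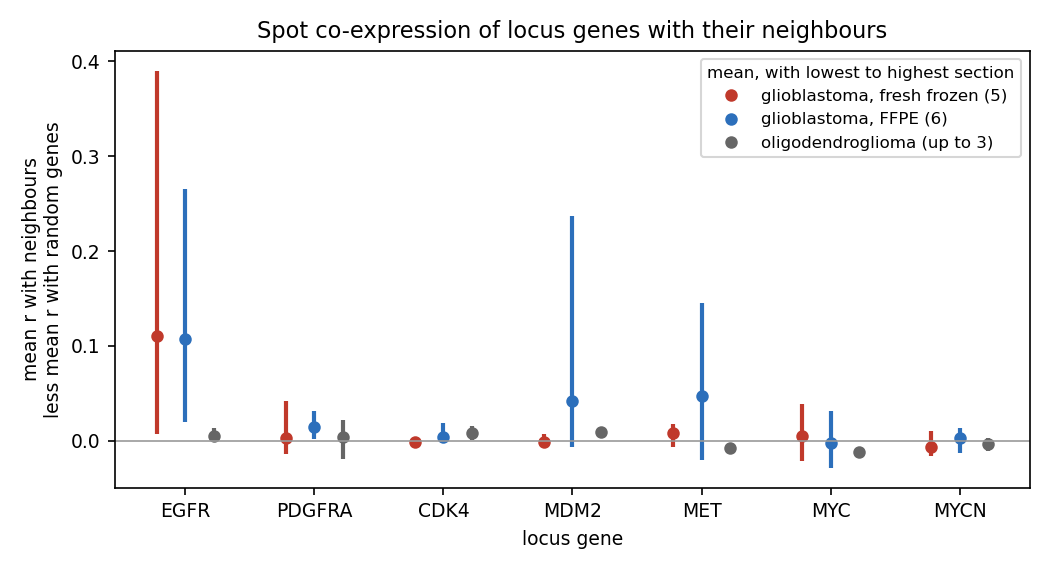
Mean correlation across spots of 7 locus genes with their chromosomal neighbours, less that with random genes of similar expression, as the mean (point) and the lowest to highest section (line) in fresh frozen glioblastoma, FFPE glioblastoma and oligodendroglioma. EGFR lies above 0 in every glioblastoma section, from 0.00701 to 0.390.

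Gene programmes occupied related or separate spots within the 11 glioblastoma sections. Hypoxia and mesenchymal scores were positively related (mean partial r 0.420 ± 0.174, SD, above 0 in 11 of 11), as were endothelial with vessel wall and matrix scores (0.518 ± 0.178, 11 of 11) and astrocytic with oligodendrocyte progenitor scores (0.430 ± 0.126, 11 of 11). Hypoxia was negatively related to proliferation (-0.281 ± 0.190, below 0 in 11 of 11) and to endothelial scores (-0.201 ± 0.118, below 0 in 10 of 11). Proliferation was positively related to oligodendrocyte progenitor scores (0.329 ± 0.243, 10 of 11), and means were smaller for mesenchymal with macrophage or microglia scores (0.222 ± 0.221, above 0 in 8 of 11), neuron with myelin scores (0.135 ± 0.197, 9 of 11) and T cell with macrophage or microglia scores (0.0722 ± 0.0563, 10 of 11). All 9 pairs passed the exact two-sided sign-flip permutation test after adjustment, with adjusted p from 0.00220 to 0.0205. The test was against 0, and no background of unrelated gene lists was subtracted. Pairs of autosome shares had a median r that averaged 0.117 in these sections and 0.196 in the FFPE ones. The smaller positive means are therefore not shown to exceed such a background. The mesenchymal and macrophage or microglia relation averaged 0.0589 in fresh frozen sections, above 0 in 2 of 5 (exact permutation, adjusted p = 0.688), and 0.357 in FFPE sections, above 0 in 6 of 6 (adjusted p = 0.0469). Without the depth term the T cell and macrophage or microglia pair did not pass (0.0488, exact permutation, adjusted p = 0.0840). There the relation of hypoxia to endothelial scores was -0.121, that of mesenchymal to macrophage or microglia scores 0.382 and that of neuron to myelin scores 0.211. The last was 0.0849 without glioblastoma replicate 3, and by rank correlation hypoxia and endothelial scores had a mean of -0.131. Spots hold several cells, so these are relations between regions of tissue. In oligodendroglioma the astrocytic and oligodendrocyte progenitor relation averaged -0.187 ± 0.293 and the neuron and myelin relation -0.228 ± 0.217 (n = 3, not tested). Among the 5 fresh frozen sections alone no pair passed, where 5 sections cannot give an exact sign-flip p under 0.0625, and among the 6 FFPE sections 6 pairs passed.

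**Figure D4:**
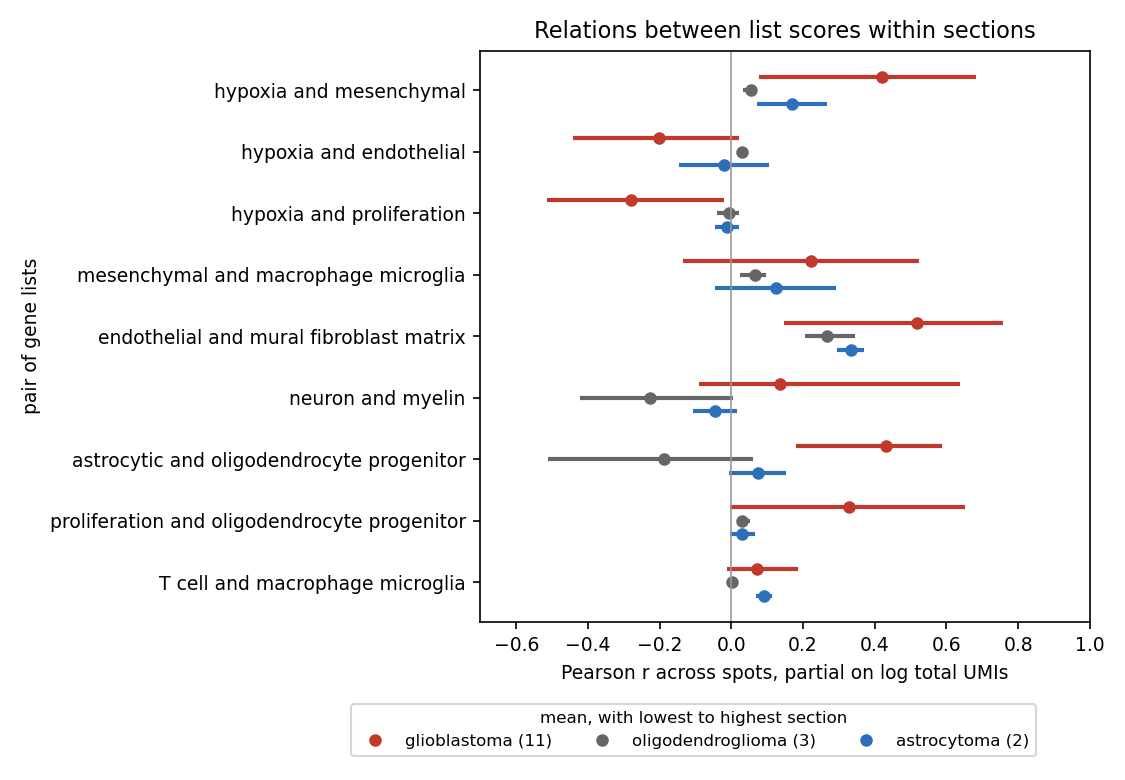
Pearson correlation across spots, partial on total UMIs, between the scores of 9 pairs of gene lists, as the mean (point) and the lowest to highest section (line) in 11 glioblastoma, 3 oligodendroglioma and 2 astrocytoma sections. In glioblastoma the hypoxia and proliferation pair lies below 0 in every section and the endothelial and vessel wall pair above 0.

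Hypoxia genes had a higher degree of spatial clustering in glioblastoma than in oligodendroglioma, in a comparison that did not pass adjustment. Moran's I, which is near 0 for no clustering, averaged 0.610 ± 0.0642 (SD, n = 5) for the hypoxia list in glioblastoma and 0.0475 ± 0.0106 (n = 3) in oligodendroglioma, after every spot was thinned to 1000 UMIs. Without thinning the values were 0.769 ± 0.0606 and 0.191 ± 0.0328. Vessel wall and matrix genes (0.404 ± 0.147 against 0.0740 ± 0.0834), mesenchymal genes (0.402 ± 0.190 against 0.0442 ± 0.0250) and proliferation genes (0.0734 ± 0.0298 against 0.00359 ± 0.0155) had the same order. Neuron genes had a higher mean in oligodendroglioma (0.460 ± 0.129 against 0.213 ± 0.299, or 0.0818 without glioblastoma replicate 3), as did red blood cell genes (0.493 ± 0.0536 against 0.288 ± 0.146). The exact two-sided permutation test over 56 splits gave p = 0.0179 for hypoxia, mesenchymal, proliferation and vessel wall genes, the smallest it can give, and 0 of 16 lists passed adjustment (adjusted p = 0.0714 for these 4). On slides D and G the hypoxia means differed by 0.594 and 0.518 and the neuron means by -0.167 and -0.413. Without thinning 6 lists passed, and thinning left out 2274 of 15950 glioblastoma and 531 of 10704 oligodendroglioma spots with fewer UMIs. Thinning made total UMIs per spot equal but not the counts of a list, and Moran's I can fall where a list has few counts. The hypoxia, mesenchymal, vessel wall and proliferation lists were also expressed higher in glioblastoma, and the neuron and red blood cell lists lower. Spatial clustering and expression level therefore cannot be told apart here.

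**Figure D5:**
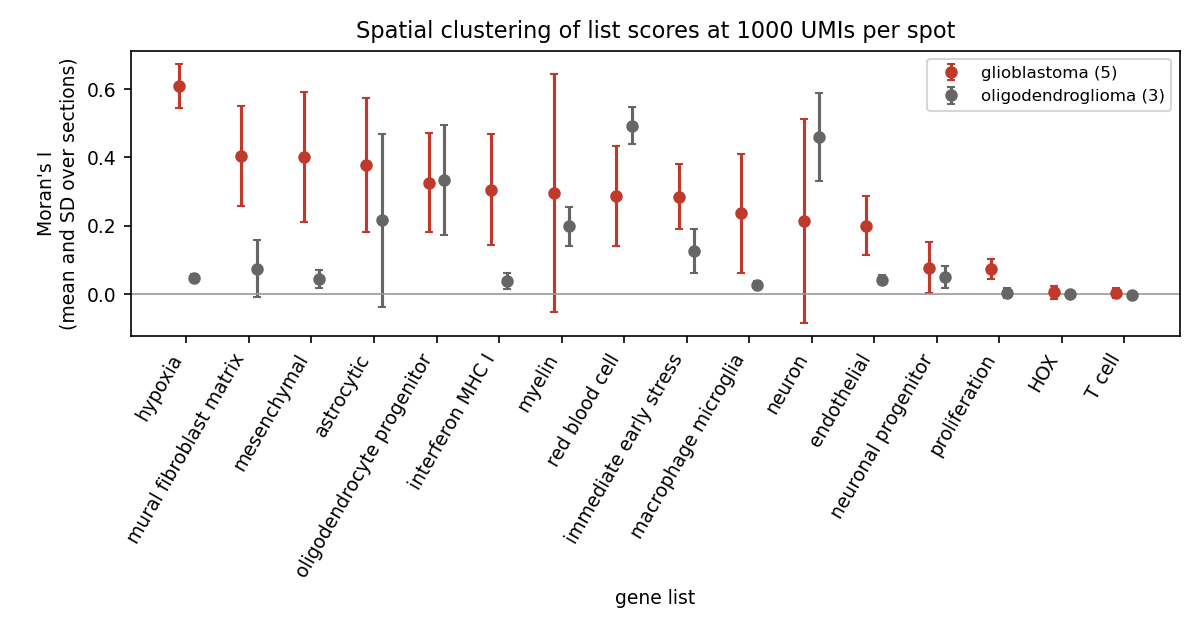
Moran's I of 16 gene list scores over neighbouring spots at 1000 UMIs per spot, as mean and SD over 5 glioblastoma and 3 oligodendroglioma sections. The hypoxia list lies highest in glioblastoma at 0.610 and at 0.0475 in oligodendroglioma.

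Among single genes, VEGFA, GFAP and NDRG1 had the best ranks of spatial pattern in fresh frozen glioblastoma. Across the 5 fresh frozen sections, the angiogenic growth factor gene VEGFA had the best mean rank of Moran's I among 4147 genes (mean I 0.574, from 0.314 to 0.724), followed by the astrocyte filament gene GFAP (0.518) and the hypoxia gene NDRG1 (0.478). IGFBP5, CHI3L1, VIM, MALAT1, SPP1, GAPDH and S100B completed the first 10. In the authors' deposited table for the 6 FFPE sections, GFAP (mean I 0.709) and CHI3L1 (0.658) ranked first among 18018 genes, followed by the matrix proteoglycan gene BCAN (0.559) and the secreted phosphoprotein gene SPP1 (0.545), with CLU, CKB, S100B, PTPRZ1, C1orf61 and AQP4 also among the first 10.

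The deposited clusters divided each fresh frozen glioblastoma section into regions. In 4 of the sections a region was led by vessel wall genes, collagens or the matrix protease gene MMP9. These genes were MMP9 (16.7-fold over the rest of the section), PLVAP and RGS5 in replicate 1 (8.12% of spots) and COL1A2 (25.2-fold), COL1A1 and ITGA1 in replicate 2 (4.02%). They were COL3A1 (16.5-fold), PLVAP and COL1A1 in replicate 4 (5.05%) and MMP9 (9.62-fold), PLVAP and FLT1 in replicate 5 (8.77%). Heat shock genes led a region in replicates 1 and 2, with HSPA6 19.1-fold and 10.4-fold higher in 5.40% and 5.26% of spots. In replicate 3, neuronal genes led by SNAP25 (40.7-fold) marked 9.66% of spots and myelin genes led by MBP (9.58-fold) marked 8.56%. In replicate 1, LANCL2 (29.8-fold) and EGFR (27.2-fold) led a region of 154 spots, 4.28% of the section. Regions led by MALAT1 or MTRNR2L12, the latter a nuclear gene with near-identical mitochondrial copies, had low median UMI counts, such as 240.5 in 21.1% of the spots of replicate 4.

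The diffuse midline glioma section is 1 sample, so no test was made and intervals cover counting error only. By the fixed rule of size, 13 genes were higher and 0 lower than in all 10 other fresh frozen sections. DLK1, a Notch-family ligand gene of progenitor cells, had 219.7 CPM (95% exact Poisson interval 213 to 227), 24.9-fold above the next highest section at 8.82 CPM. The complement gene C7 (104 CPM, 99.2 to 109) was 8.23-fold higher and SCFD2 (97.2 CPM, 92.7 to 102) 7.19-fold higher. Matrix genes were among the rest, with CTHRC1 6.27-fold, ISLR 5.66-fold, MFAP2 4.31-fold, FBLN2 4.26-fold and the cartilage proteoglycan gene ACAN 4.16-fold higher, as were FAM89A, TMEM255A, GPR137B, CITED1 and PHLDA2 at 4.12-fold to 6.21-fold. The summed vessel wall and matrix list (12554 CPM, 12502 to 12605, against at most 9124 in the others) and endothelial list (1518.5 CPM, 1501 to 1536, against 223 to 1477) ranked first of 11 sections.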

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

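Leaving out sections from the comparison of EGFR with 7p was the only test in this part chosen after its result was seen. Among 129 groups of sections tested for a section far from the others, 4 had one, and chance alone gives about 1 in 20, or 6.45. CRTAC1, among the lower genes in glioblastoma, had 1 of 5 glioblastoma sections far above the rest, at a gap of 0.724 of the group's range. The CDK4 difference between neighbours and random genes had such a section among the 6 FFPE sections (0.818 of the range), and so had the MDM2 difference (0.903 of the range). The mesenchymal and macrophage or microglia relation was lower in the 5 fresh frozen than in the 6 FFPE glioblastoma sections, at 0.0589 and 0.357, a difference of -0.298 (exact permutation p = 0.0281), which did not pass adjustment over 17 such differences (adjusted p = 0.478).

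The coupling of EGFR to its chromosomal neighbours in fresh frozen glioblastoma had 1 of 5 sections far above the others, at a gap of 0.768 of the range. A signal of the whole arm 7p, such as a gain of chromosome 7 that varies between spots, could give shared spots without any focal event. Against expression-matched 7p genes more than 10 Mb away the neighbours still correlated more, by 0.0997 ± 0.130 (SD, n = 11), above 0 in 10 of 11 sections (exact sign-flip permutation p = 0.00195), which argues against the arm as the whole source. A focal amplification that differs between parts of a tumour, inside or outside the chromosome, is a hypothesis that expression alone does not test, and shared regulation of neighbouring genes stays open too. Leaving out any one section kept this difference from 7p genes between 0.0701 and 0.110, and that from random genes between 0.0807 and 0.119.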

How the results depend on the processing

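The slide term was the only test in this part chosen after the data were seen. Of 185 alternative values of the comparisons, 144 kept their direction and side of the threshold or stayed within 1.5 times the count. With the slide term the counts of genes were 634 for glioblastoma against oligodendroglioma, 0 against astrocytoma (692 unadjusted in edgeR) and 0 for astrocytoma against oligodendroglioma (2017 unadjusted). Fitting only the 2 groups gave 2 genes for glioblastoma against astrocytoma and 0 for astrocytoma against oligodendroglioma (2847 unadjusted). DESeq2 gave 1755 and 1623 in those contrasts, and relative log expression scaling gave 0 in the latter (3382 unadjusted). With an estimated correlation 0, 0 and 0 lists passed in the 3 contrasts, and fry gave 10, 2 and 0. In the first contrast fry ended the myelin and stress calls (adjusted p = 0.0561 each) and those of macrophage and microglia (0.102) and T cell genes (0.177). The 1p and 19q coupling was 0.266 with shares as means over genes. Fresh frozen or FFPE sections alone gave 0 and 0 loci, and fresh frozen sections alone 0 relations, where fewer sections raise the smallest possible p. Without thinning, 6 lists passed for Moran's I. Apart from fewer sections, and the slide term between glioblastoma and oligodendroglioma, where the errors were wider, the cause was not tested.

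Leaving out 1 section at a time gave 2300 to 5240, 3 to 507 and 0 to 971 genes in the 3 contrasts, in the order above, and 12 to 15, 6 to 11 and 5 to 14 lists. The number of arms ranged from 8 to 14 for glioblastoma and that of loci from 1 to 2, and the 1p and 19q coupling ranged from -0.308 to 0.126. List tests that pointed the other way were hypoxia against astrocytoma without astrocytoma replicate 1 (adjusted p = 0.208, range 1.29e-08 to 0.208), hypoxia (0.519, range 4.40e-08 to 0.519) and neuronal progenitor (0.934, range 0.000640 to 0.934) between astrocytoma and oligodendroglioma without astrocytoma replicate 2, and myelin without astrocytoma replicate 1 (0.0112, range 0.000159 to 0.968). The cause was not tested. With 2 astrocytoma sections, leaving one out assumes that the other varies like the other groups. Arm 10p had no value with genes of at least 50 CPM, since too few genes were left. Of 1161 alternative values of named genes past the test, 880 kept their call and 281 lost it, 75 values of the other named genes gained one, and 0 reversed.

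With the replicate number of the titles as a block, 2344, 0 (2803 unadjusted) and 0 (1944 unadjusted) genes and 12, 10 and 11 lists passed in edgeR and camera. The list calls that ended were T cell (adjusted p = 0.412) and stress (0.0583) for glioblastoma against oligodendroglioma, vessel wall and matrix against astrocytoma (0.113) and T cell for astrocytoma against oligodendroglioma (0.0538). Same-numbered sections had no consistent likeness. In the first contrast their deviations had correlations of 0.0546, -0.123 and -0.170. The highest with another number were 0.0355, 0.0896 and 0.155. Same-numbered sections had correlations of 0.200 and -0.0945 in the second contrast and of -0.0330 and 0.00483 in the third. With 2 astrocytoma sections their deviations mirror each other, so those contrasts tell little about pairing. Depth was 5572453 to 10117287 UMIs per section in astrocytoma and the median per spot was 1460.5 in glioblastoma replicate 4, and how far depth limits the calls was not tested.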

Other observations

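The slide term in the gene comparison and the slide tests of 1p and 19q each alone were chosen only after the data were seen, and the other tests in this part were not, although the limits on their spread, and on how far a setting must move the genes, were set after values had been seen. The deposited clusters of the oligodendroglioma sections included regions led by neuronal genes in each. CCK, a neuropeptide gene, LY6H and the glutamate transporter gene SLC17A7 led 24.1% of the spots of replicate 1, and PCP4 (4.75-fold over the rest of the section), NEFM (4.53-fold) and ENC1 (4.28-fold) led 7.5%. HPCAL1 (4.76-fold), PTK2B and the neuronal kinase gene CAMK2A (2.76-fold) led 18.8% of replicate 2, and NPTX2 (6.63-fold), HS3ST2 (6.21-fold) and NNAT (5.64-fold) led 31.2% of replicate 3. Progenitor genes GPR17 (1.70-fold), SMOC1 and DLL3 (1.64-fold) led 14.5% of replicate 1, and the chemokine genes CCL4L2 (4.49-fold) and CCL4 (3.83-fold) led another 12.8%. In replicate 3, SLC14A1 (4.52-fold) and the astrocyte gap junction gene GJA1 (3.65-fold) were among the leading genes of 14.8%, and HBB (14-fold) led 18.4%. The smooth muscle gene TAGLN (13-fold) and HBA2 (11.6-fold) led 13.3% of replicate 2.

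In astrocytoma replicate 1, matrix genes IGFBP6 (20.6-fold), COL1A2 (16.5-fold) and MGP (13-fold) led 19.7% of spots, and CCK (5.21-fold), VSNL1 and VGF led 15.8%. In replicate 2, genes of protein folding in the endoplasmic reticulum, HSPA5 (7.01-fold), PDIA4 (6.63-fold) and HYOU1 (6.32-fold), led 10.3%, and COL4A1 (3.27-fold), NPY and SERPINA3 led 20.8%. In the diffuse midline glioma section, COL1A1 and COL3A1 (12.4-fold each) and MMP9 (12-fold) led 22.2% of spots, and PPDPFL (28.1-fold) with the hypoxia genes HILPDA (11.8-fold) and NDRG1 (11.7-fold) led 15.2%.

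For the genes that differed between glioblastoma and oligodendroglioma, 1 of 56 splits of the 8 sections, the real one, gave as many as 5049 genes. The highest other split gave 7. This argues against a chance division of these sections but cannot exclude it, since 1 of 56 is the smallest share possible. The other splits also mix both groups, which widens the spread and lowers their counts. A difference between capture slides as the whole source is argued against by the folds, since with the slide as a term the median ratio of log2 fold changes to those without it was 0.942 (quartiles 0.856 to 1.03), although the number of genes was 634, of which 623 were among the 5049. Over the 5049 genes the median size of the log2 fold change was 2.10 without and 1.99 with the term, and the median SE 0.46 and 0.55, with 7 and 4 residual degrees of freedom, so calls ended through a wider error more than smaller folds. Leaving out mitochondrial and ribosomal protein genes gave a median ratio of 1.001 and 5060 genes, but this cannot exclude RNA quality, since scaling absorbs 1 factor per section, the median of all genes moved only from 0.117 to 0.0876, and the mitochondrial share separates the groups fully. RNA quality and tumour type therefore cannot be told apart here, and a larger share of neurons and myelin in the oligodendroglioma sections may also contribute, with the tumour type a hypothesis among these.

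Lower expression of 1p and 19q in oligodendroglioma did not pass adjustment over arms. Neurons and myelin in the sections could shift arm scores. In the spots of each section poorest in those genes the mean difference of both arms was -0.564 against -0.468 over all spots, a ratio of 1.21. The difference thus did not shrink in poorer spots. These spots were chosen within each section, and the neuron and myelin content left in them was not compared between groups. The test therefore cannot exclude these cells as a source. A slide effect as the whole source is argued against for 1p, which lay below the other sections of its slide on all 3 slides. The differences were -0.489 on D, -0.307 on E and -0.534 on G, each beyond the spread (0.000564, 0.0399 and 0.0550). That spread rests on 2 or 3 other sections per slide, so passing it is weak evidence. Each slide held 1 oligodendroglioma section, and 1p scores had an SD of 0.128 between oligodendroglioma sections. For 19q a slide effect, the oligodendroglioma type and a high 19q score in the glioblastoma sections compared with it cannot be told apart. The mean 19q score was 0.338 in glioblastoma and -0.355 in oligodendroglioma. Slide E, which held no glioblastoma, gave a 19q difference of -0.0680 (spread 0.283), where the other sections had a mean score of -0.204. The mean of both arms on slide E, -0.187, on which the test was first written, let 1p stand in for 19q. Loss of both arms, which defines this tumour type, is a hypothesis that stays open beside these, and expression does not measure it directly.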
